A study of Homo sapiens with 4 samples.

How the data were processed

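LNCaP-SL cells, grown per the labels in RPMI with 10% fetal bovine serum at 5% CO2, were given csEV or PBS for 24 h. The csEV were isolated by 5 centrifugation steps, total RNA was extracted with Trizol and libraries were made by Illumina protocols, per the labels. The instrument, the read length and whether poly-A RNA was selected are not given in the sources used here. The deposited table holds whole-number read counts per gene for 18660 genes, with 1 column for each of the 4 libraries, and the authors deposited it without normalization. The submitters' processing notes name STAR 2.7.1a, HTSeq 0.12.4, DESeq2 1.26.0 and the genome build GRCh38. The role and order of these tools, the annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. The control columns were assigned to the PBS group because PBS is the only control the labels name, with the replicate numbers as in the column names.

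Of the 18660 Ensembl identifiers, 18628 were matched to a symbol and 32 were not. Identifiers were looked up in GENCODE v29 (GRCh38), which held 18655 of them, 18599 as protein coding, and all coordinates come from it. It may not be the release the authors used. Reads from overlapping genes on opposite strands cannot be told apart if strand was not used. Of the 223 genes that the naming rule takes, 45 share exonic sequence with another protein-coding gene, 17 of them over at least 10% of their exonic length, and their counts are uncertain. The same holds for genes with near-identical copies.

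Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (12740 of 18660; the other 5920 were not tested), libraries were scaled with TMM factors, and csEV was compared with PBS by the quasi-likelihood test, two-sided, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was said to rise or fall at an adjusted p under 0.05. Group levels are means of TMM-scaled CPM ± SD with n = 2, unless CPM of the deposited total is named. Fold changes come from the fitted model. The standard error of a log2 fold change was derived from the log2 fold change and the quasi-likelihood statistic. With 2 libraries per group, an exact permutation test of 1 gene cannot reach 0.05, so the test rests on the spread pooled across genes.

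For gene groups, 52 lists were fixed, of which 49 had at least 5 tested members. They were tested with camera (limma 3.58.1, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the lists. The test was repeated with a correlation estimated from the data and with fry, which tests whether members move, on balance, one way without comparing them with other genes. Each list is also given as the count of members that rose or fell over all tested genes and adjusted over the list alone. The lists, the tests, the groups and the rule for named genes were chosen before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and groups that did not overlap. It also took the 5 smallest p in each direction under the same CPM rule, up to 4 tested members with the smallest p from each list past the threshold or named, 14 fixed genes, among them KLK3, KLK2, TMPRSS2, FKBP5, FOLH1, MYC, MKI67, VIM, CDH1, CD9, CD63 and CD81, and the most abundant gene of each list of other cell types. Genes without an official symbol and Y-chromosome genes and XIST were skipped, and some genes and lists that the rule takes are not reported here. Of the fixed genes not described further, KLK2 had 17, 19, 13 and 21 counts in PBS replicates 1 and 2 and csEV replicates 1 and 2 (quasi-likelihood adjusted p = 0.972), and FKBP5 stood at 101 ± 5.54 CPM with PBS and 107 ± 1.87 CPM with csEV (SD, n = 2; adjusted p = 0.522).

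The alternatives were the replicate number as a block, RLE and upper-quartile factors or library size alone, every gene with a count or at least 1 CPM in all 4 libraries, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, an adjusted p under 0.1, and each library left out in turn. In the last case the group with 1 library is assumed to vary like the other. The block with crossed numbers, the correction of list tests for GC content and exonic length, and the counts of list members without each library were added after the data were seen. The correction removed trends over GC content, exonic length and expression. Lists were then tested with cameraPR, a form of camera that starts from the per-gene statistics. The procedure was tested on simulated data drawn from the means and depths of these libraries, each gene independently of the others. The quasi-likelihood test recovered 67% of 100 genes changed by 0.5 on the log2 scale and 88% of 100 genes changed by 1, with 5 false calls among 12504 genes, and called 0 of 12501 genes (quasi-likelihood, adjusted) with no change simulated. The changed genes were drawn only from genes above a minimum expected count, so the recovery does not hold for tested genes of fewer counts. A list raised by 0.3 gave a camera adjusted p of 3.68e-50, against 0.212 with an estimated correlation and 0.379 with fry, so these last tests missed a change of that size with 2 libraries per group.

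Totals per library lay between 7792574 and 8290966 counts, so that 3 counts, the upper limit that a count of 0 allows, came to between 0.362 and 0.385 CPM. The reads carry no molecular identifiers in the sources used here, so floors and counting intervals cover counting error only. The 10 most abundant genes took between 3.78% and 3.83% of the counts, the 13 mitochondrially encoded genes between 0.546% and 0.580%, and 82 ribosomal protein genes between 2.87% and 2.92%. Pearson's r of log2 CPM across genes lay between 0.990 and 0.995 for pairs of libraries, and genes are not independent replicates. The first principal component (51.4% of the variance) separated the groups, at -9.07 and -18.1 for PBS replicates 1 and 2 and at 13.8 and 13.4 for csEV replicates 1 and 2. The second (26.1%) did not, at 14.3 and -10.3 for PBS replicates 1 and 2 and at -8.25 and 4.26 for csEV replicates 1 and 2.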

Results

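Gene expression was measured by RNA sequencing in LNCaP-SL cells after 24 h with circulating small extracellular vesicles (csEV) or with phosphate-buffered saline (PBS), the vehicle. LNCaP is a human prostate cancer line, and the labels describe LNCaP-SL as an aggressive subline of it. Several genes of prostate epithelium were low in all 4 libraries and mesenchymal transcripts were abundant, as described below. The identity of the cells and the species of the reads therefore stay open. The changes below are not shown to be those of prostate cancer cells. Small extracellular vesicles are membrane particles that cells release and that carry protein and RNA. The labels do not name the donor or the body fluid of the csEV. Each group had 2 libraries, and the labels do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The deposited counts per library came to 8290966 and 7952314 for PBS replicates 1 and 2 and to 7843306 and 7792574 for csEV replicates 1 and 2. Between 16831 and 16923 of the 18660 genes in the table had at least 1 count in a library. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 3.02 over 10535 genes between the PBS libraries and 1.71 over 10493 genes between the csEV libraries. They were therefore not counted as 1 library deposited in 2 columns, which does not show that they came from separate cultures. Levels are given in CPM, a gene's counts scaled to the same total in each library. Between libraries of different groups the same ratio lay between 4.78 and 7.82.

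The comparison asks which genes changed when the cells were given csEV for 24 h. Of 32 interferon-response genes and 34 mitotic genes tested, 19 and 32 rose with csEV, and of 32 proteasome genes and 37 lysosomal genes, 19 and 11 fell. Each of these 4 lists passed camera and had an adjusted p = 0.648 with an estimated correlation. IFIT1, an interferon-induced RNA-binding protein (ENSG00000185745, GRCh38 chromosome 10, 89392546 to 89406486), had the largest rise among the named genes, from 7.01 ± 0.189 CPM (SD, n = 2) to 25.4 ± 0.779 (SD, n = 2), or 3.61-fold. CD68, a lysosomal glycoprotein used as a macrophage marker (ENSG00000129226, chromosome 17, 7579467 to 7582113), had the largest fall among them, from 5.91 ± 0.649 CPM (SD, n = 2) to 1.85 ± 0.0944 (SD, n = 2), or 3.17-fold. Of 12740 genes tested with edgeR's quasi-likelihood test, 1201 (9.43%) passed a Benjamini-Hochberg adjusted p of 0.05, 638 higher and 563 lower after csEV. The balance of directions depended on the scaling, with 610 higher and 651 lower with upper-quartile factors and 697 higher and 447 lower with library size alone. Most changes were small. The median fold of the 1201 genes was 1.27, and 63 genes changed at least 2-fold, 50 of them upward. In 1197 of the 1201 genes the csEV and PBS libraries did not overlap, which a small p in the same comparison nearly requires. Of all tested genes 50.3% did not overlap, where chance gives 33.3%. Without PBS replicate 2 the count of changed genes was 125, and without each of the other libraries in turn it lay between 596 and 663. DESeq2 called 544 genes, and a quasi-likelihood test over every gene with a count called 371.

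Interferon-stimulated genes gave most of the largest rises. RSAD2 (viperin, an antiviral enzyme; ENSG00000134321, chromosome 2, 6865806 to 6898239) went from 14.6 ± 0.432 to 44.1 ± 2.24 CPM (SD, n = 2), a log2 fold change of 1.60 ± 0.12 (SE; quasi-likelihood adjusted p = 1.09e-08). IFI44 (ENSG00000137965, chromosome 1, 78649796 to 78664078) rose 3.41-fold and IFIT3 (ENSG00000119917, chromosome 10, 89327894 to 89340971) 2.64-fold. SAMD9L, an interferon-induced growth regulator on chromosome 7, was expressed far higher and rose from 234 ± 18.7 to 432 ± 16.9 CPM (SD, n = 2; log2 fold change 0.88 ± 0.06 SE). The chemokines CXCL9 and CXCL10, which attract T cells through the receptor CXCR3, rose 2.51-fold and 2.39-fold, the latter from 4.94 ± 1.05 to 11.9 ± 1.60 CPM (SD, n = 2). Of 32 tested members of the interferon list, 19 rose and the other 13 did not pass. Adjusted over the list alone, 22 rose. The list median log2 fold change was 0.76 (camera adjusted p = 2.37e-42). The adjusted p = 0.648 with an estimated correlation. OAS3, a sensor of double-stranded RNA, rose from 50.7 ± 1.79 to 103 ± 1.12 CPM (SD, n = 2). Without PBS replicate 2, 12 members rose and CXCL10 lost its call (quasi-likelihood adjusted p = 0.0801). Members of the IFIT, GBP and OAS families have close paralogs, so counts of single members, above all IFIT1B (1.63 ± 0.13 SE on the log2 scale), are uncertain.

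**Figure D1:**
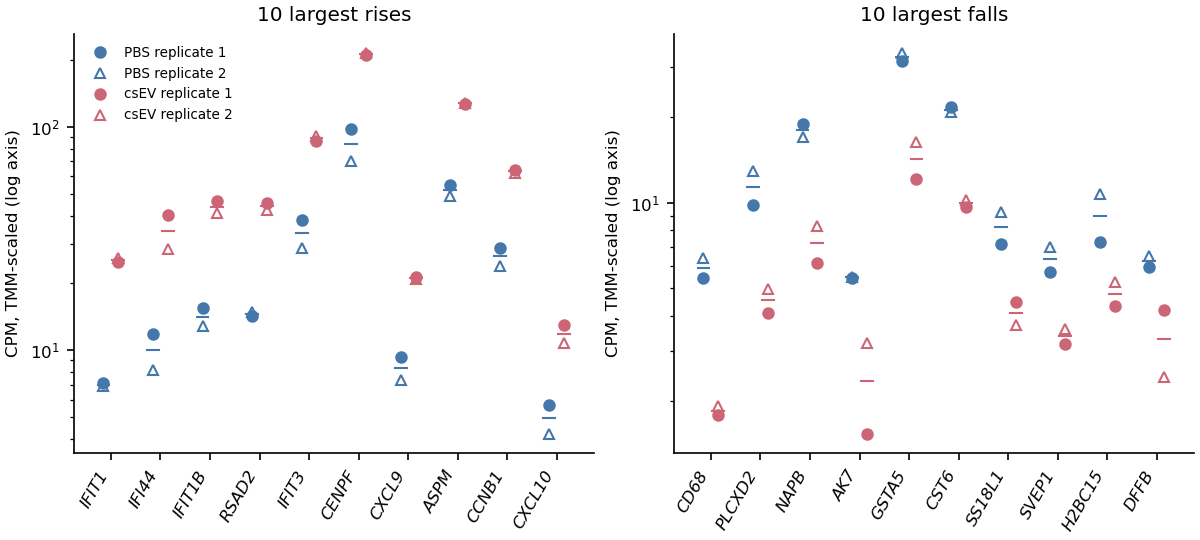
Levels in CPM scaled by TMM factors, on a log axis, for the 10 genes with the largest rises (left) and the 10 with the largest falls (right) among genes of at least 5 CPM in a group that passed the test. Each point is a library, filled circles for replicate 1 and open triangles for replicate 2. Blue marks PBS, red marks csEV and short lines mark group means. The csEV and PBS libraries did not overlap in any of the 20 genes, because the naming rule required it.

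Mitotic genes moved together. CENPF, a kinetochore protein (ENSG00000117724, chromosome 1, 214603195 to 214664588), rose 2.52-fold, from 84.2 ± 19.6 to 212 ± 3.28 CPM (SD, n = 2). ASPM, a spindle pole protein (ENSG00000066279, chromosome 1, 197084128 to 197146694), had the smallest p of all genes and rose 2.45-fold, from 52.1 ± 4.37 to 128 ± 0.924 CPM (SD, n = 2; log2 fold change 1.29 ± 0.08 SE, quasi-likelihood adjusted p = 6.81e-10). CCNB1, the cyclin that starts mitosis (ENSG00000134057, chromosome 5, 69167010 to 69178245), rose 2.40-fold. CENPE, a kinetochore motor, rose 1.98-fold, and the proliferation marker MKI67 rose 1.56-fold, from 93.5 ± 12.1 to 146 ± 4.93 CPM (SD, n = 2). Of 34 tested members of the mitosis and G2/M list, 32 rose and NUF2 and CCNF did not pass. Adjusted over the list alone, all 34 rose. The list median was 0.74 on the log2 scale (camera adjusted p = 1.33e-97), and the adjusted p = 0.648 with an estimated correlation. The list also differed between the PBS libraries, with a median log2 CPM 0.18 higher in PBS replicate 1 than in replicate 2. Without PBS replicate 2, 22 members rose.

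In the list of S phase and DNA replication fewer genes passed the test. RRM1 and RRM2, the subunits of ribonucleotide reductase, rose 1.20-fold and 1.24-fold, and the primase subunit PRIM1 rose 1.37-fold, from 46.9 ± 9.03 to 64.2 ± 2.04 CPM (SD, n = 2). CCNE2, a cyclin of the G1 to S transition, fell 1.33-fold, from 104 ± 8.58 to 78.5 ± 1.35 CPM (SD, n = 2). Of 35 tested members 7 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell (median 0.14; camera adjusted p = 0.00408). The adjusted p = 0.729 with an estimated correlation. The PBS libraries differed here by a median of 0.23, more than the groups did, and without PBS replicate 2 the median was 0.02 (camera adjusted p = 0.875) and 0 members rose and 1 fell by the quasi-likelihood test. Without csEV replicate 2 the camera adjusted p was 0.0685 and 2 members rose. Exons of CCNE2 overlap INTS8 on the opposite strand, and those of PRIM1 and RRM2 overlap other gene models.

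The largest falls were in genes of low or moderate expression. CST6 (cystatin E/M, a secreted protease inhibitor; ENSG00000175315, chromosome 11, 66011841 to 66013505) fell from 21.3 ± 0.558 to 9.94 ± 0.383 CPM (SD, n = 2), and NAPB, a SNARE recycling factor, fell 2.50-fold to 7.20 ± 1.55 CPM (SD, n = 2). GSTA5 and GSTA1, glutathione transferases encoded in one cluster on chromosome 6, fell 2.30-fold and 1.87-fold, the latter from 54.5 ± 3.26 to 29.1 ± 3.94 CPM (SD, n = 2). PLCXD2 fell 2.51-fold, AK7 2.31-fold, SS18L1 2.01-fold, and SVEP1, H2BC15 and DFFB each 1.87-fold. CST6, NAPB, GSTA5 and GSTA1 passed the test without each library in turn. CD68 and PLCXD2 did not pass without PBS replicate 2 (quasi-likelihood adjusted p = 0.0745 for each), and AK7, SS18L1, SVEP1, H2BC15 and DFFB did not pass there either (adjusted p from 0.199 to 0.304). Of these 5, AK7, SVEP1 and DFFB also did not pass without PBS replicate 1, AK7, SVEP1 and H2BC15 without csEV replicate 1, and SS18L1, SVEP1 and DFFB without csEV replicate 2, with adjusted p up to 0.43 for DFFB. The GSTA genes and the histone gene H2BC15 have near-identical copies, so their counts are uncertain. Among the 5 falls with the smallest p was DST, a cytoskeletal linker, which fell 1.24-fold from 2659 ± 108 to 2142 ± 47.5 CPM (SD, n = 2). TMEM106B, a lysosomal membrane protein, fell 1.44-fold and GTF2H1, a subunit of the transcription factor TFIIH, 1.36-fold.

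In the proteasome list, PSMC2, an ATPase of the regulatory particle (ENSG00000161057, chromosome 7, 103344254 to 103369395), fell 1.28-fold, from 426 ± 20.3 to 332 ± 7.17 CPM (SD, n = 2; quasi-likelihood adjusted p = 8.37e-05). PSMA7 fell 1.27-fold and PSMD11 1.24-fold. Of 32 tested members 19 fell and the other 13 did not pass, and adjusted over the list alone 23 fell (median -0.23; camera adjusted p = 1.37e-13). The adjusted p = 0.648 with an estimated correlation. The count of members that fell was 1 without PBS replicate 2, 3 without csEV replicate 2 and 8 without csEV replicate 1.

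In the lysosome list, ATP6V1A, the catalytic subunit of the proton pump (ENSG00000114573, chromosome 3, 113747019 to 113812056), fell 1.33-fold, from 504 ± 32.7 to 378 ± 12.8 CPM (SD, n = 2; quasi-likelihood adjusted p = 1.42e-05). CTSA (cathepsin A) fell 1.43-fold, although its exons overlap a neighbour on the opposite strand. CD63, a tetraspanin of lysosomes and of extracellular vesicles, fell 1.20-fold, from 640 ± 35.3 to 531 ± 13.9 CPM (SD, n = 2). Of 37 tested members 11 fell and 1 rose, and adjusted over the list alone 17 fell and 1 rose (median -0.16; camera adjusted p = 5.26e-06). The adjusted p = 0.648 with an estimated correlation. In the autophagy list 5 of 26 members fell and 2 rose, and adjusted over the list alone 9 fell and 2 rose (median -0.14; camera adjusted p = 0.0422, adjusted p = 0.709 with an estimated correlation). The autophagy receptor SQSTM1 fell 1.15-fold and GABARAPL2 1.28-fold, whereas the kinase gene ULK2 rose from 96.4 ± 11.4 to 120 ± 3.33 CPM (SD, n = 2). Without PBS replicate 2, 1 lysosomal member and 0 autophagy members fell by the quasi-likelihood test and the autophagy list did not pass (camera adjusted p = 0.179), nor did it pass without csEV replicate 2 (camera adjusted p = 0.195).

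**Figure D2:**
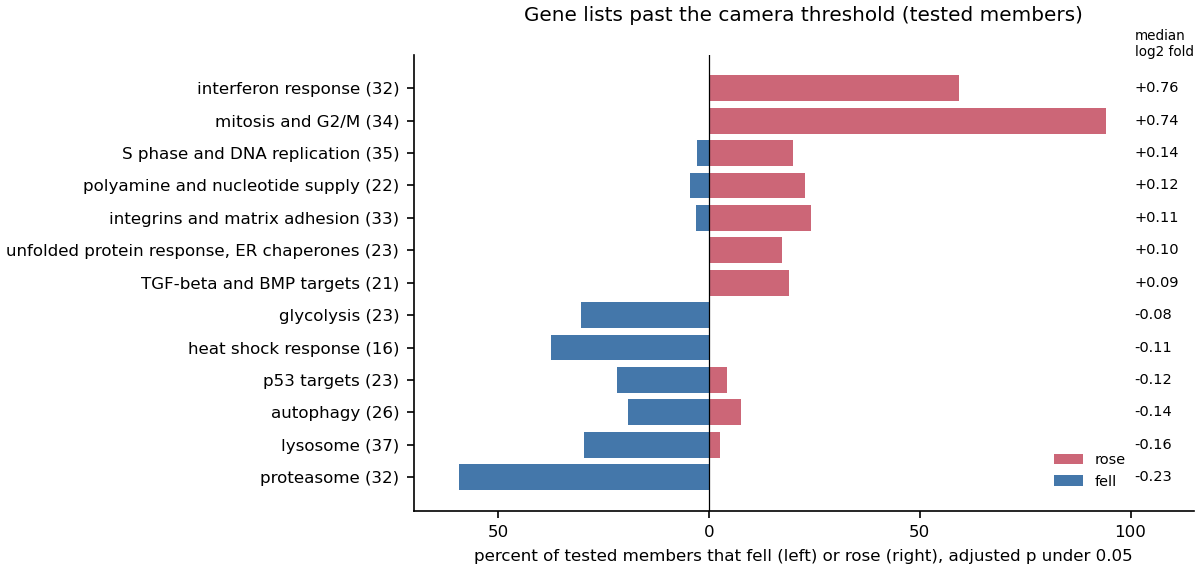
Share of tested members, in percent, that rose (red, right) or fell (blue, left) at an adjusted p under 0.05 in the 13 gene lists past the camera threshold, with the number of tested members in brackets and the list median log2 fold change at the right. The mitosis list (median 0.74) and the interferon list (0.76) stand apart from the other 11, whose medians lie between -0.23 and 0.14.

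In the heat shock list 6 of 16 tested members fell and the other 10 did not pass. HSP90AA1, the stress-inducible HSP90, fell 1.18-fold, from 1534 ± 22.8 to 1301 ± 25.3 CPM (SD, n = 2), as did the co-chaperone HSPH1, and DNAJA1 fell from 368 ± 36.8 to 303 ± 11.4 CPM (SD, n = 2). Adjusted over the list alone 7 fell and 1 rose (median -0.11; camera adjusted p = 0.0103, adjusted p = 0.648 with an estimated correlation). Among chaperones of the endoplasmic reticulum, MANF rose 1.34-fold, from 95.6 ± 3.09 to 128 ± 3.04 CPM (SD, n = 2), and the disulfide isomerase PDIA6 1.16-fold. In the unfolded protein response list 4 of 23 members rose and 19 did not pass, and adjusted over the list alone 8 rose (median 0.10; camera adjusted p = 0.00792, adjusted p = 0.709 with an estimated correlation). The heat shock list did not pass after a correction for GC content, exonic length and expression (cameraPR adjusted p = 0.0689). Nor did it pass camera without csEV replicate 2 (median -0.05). The unfolded protein response list did not pass camera without csEV replicate 1 (median 0.07). By the quasi-likelihood test 1 heat shock member fell and 0 members of the unfolded protein response list rose without PBS replicate 2.

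The basement membrane collagens COL4A2 (ENSG00000134871, chromosome 13, 110305812 to 110513209) and COL4A1 rose 1.37-fold and 1.22-fold, and ITGA6, the laminin-binding integrin subunit, rose 1.41-fold from 43.3 ± 1.0 to 61.1 ± 7.08 CPM (SD, n = 2). In the list of integrins and matrix adhesion 8 of 33 members rose and 1 fell, over all genes and adjusted over the list alone alike (median 0.11; camera adjusted p = 0.00408, adjusted p = 0.648 with an estimated correlation). LTBP1, which binds latent TGF-beta in the matrix, rose from 207 ± 16.6 to 289 ± 0.933 CPM (SD, n = 2; log2 fold change 0.48 ± 0.06 SE, quasi-likelihood adjusted p = 1.02e-05). In the list of TGF-beta and BMP targets 4 of 21 members rose, and adjusted over the list alone 5 rose (median 0.09; camera adjusted p = 0.0422, adjusted p = 0.648 with an estimated correlation). Without PBS replicate 1 and without csEV replicate 1 the TGF-beta list did not pass (camera adjusted p = 0.0873 and 0.12). Without PBS replicate 2, 0 members of the adhesion list and 1 of the TGF-beta list rose by the quasi-likelihood test. In the list of mesenchymal genes of epithelial-mesenchymal transition 5 of 21 members rose and 1 fell, and adjusted over the list alone 6 rose and 1 fell, but the list did not pass (camera adjusted p = 0.0842). COL1A1 rose from 925 ± 42.1 to 1109 ± 8.76 CPM (SD, n = 2) and MMP2, a gelatinase, fell from 88.5 ± 6.06 to 66.2 ± 2.77 CPM (SD, n = 2). The mesenchymal list passed without PBS replicate 2 (camera adjusted p = 0.0184) while 0 members rose by the quasi-likelihood test, COL1A1 among those lost (adjusted p = 0.0529). Without csEV replicate 1, 2 members rose, without PBS replicate 1, 3 rose, and MMP2 lost its call without PBS replicate 1 (adjusted p = 0.0661).

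Among p53 targets, MDM2, the ubiquitin ligase that limits p53, fell 1.37-fold from 262 ± 14.5 to 190 ± 16.2 CPM (SD, n = 2; quasi-likelihood adjusted p = 4.74e-05), TP53INP1 fell 1.45-fold and GADD45A 1.32-fold. Of 23 tested members 5 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose (median -0.12; camera adjusted p = 0.00411, adjusted p = 0.648 with an estimated correlation). Without PBS replicate 1 the list did not pass (camera adjusted p = 0.109), and without PBS replicate 2, 2 members fell and 0 rose by the quasi-likelihood test. Glycolysis genes included 7 of 23 that fell, and adjusted over the list alone 8 fell (median -0.08; camera adjusted p = 0.00792, adjusted p = 0.729 with an estimated correlation). HK1, which phosphorylates glucose, fell 1.27-fold, from 440 ± 51.7 to 347 ± 20.8 CPM (SD, n = 2). The PBS libraries differed in this list by a median of -0.20 (replicate 1 minus replicate 2), and without PBS replicate 2 the glycolysis median was 0.02 (camera adjusted p = 0.739) and 0 members fell by the quasi-likelihood test. Without csEV replicate 2 the camera adjusted p of glycolysis was 0.155 and 1 member fell. In the list of polyamine and nucleotide supply 5 of 22 members rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell (median 0.12; camera adjusted p = 0.0143, adjusted p = 0.648 with an estimated correlation). CTPS1, a CTP synthase, rose 1.18-fold, whereas SAT1, which starts polyamine breakdown, fell 1.43-fold from 192 ± 35.7 to 134 ± 6.81 CPM (SD, n = 2). This list did not pass without PBS replicate 2 (camera adjusted p = 0.196; 0 members rose by the quasi-likelihood test) or without csEV replicate 2 (camera adjusted p = 0.0685).

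Several genes of prostate epithelium were low or near the detection floor in all 4 libraries, while mesenchymal transcripts were abundant. A floor of 3 counts corresponded to between 0.362 and 0.385 CPM. The surface protein FOLH1 (PSMA) had 2, 3, 8 and 3 counts in PBS replicates 1 and 2 and csEV replicates 1 and 2, and the epithelial cadherin CDH1 had 8, 6, 8 and 8, and both genes were not tested. KLK3, which encodes prostate-specific antigen, stood at 3.07 ± 1.43 CPM with PBS and 2.17 ± 0.356 with csEV (SD, n = 2), and TMPRSS2 at 5.79 ± 0.996 and 6.56 ± 0.977 CPM (SD, n = 2). By contrast COL1A2, a fibrillar collagen chain, stood at 3545 ± 61.6 and 3402 ± 11.5 CPM (SD, n = 2; quasi-likelihood adjusted p = 0.304) and VIM (vimentin) at 1020 ± 46.6 and 1113 ± 28.1 CPM (SD, n = 2; quasi-likelihood adjusted p = 0.0661). In the prostate luminal list none of 11 passed the quasi-likelihood test (camera adjusted p = 0.96), and in the neuroendocrine list 1 of 6 fell (camera adjusted p = 0.577), a call lost without each library in turn. Of 32 genes without a rodent counterpart 11 lay under 1 CPM, against 3 of 33 conserved partner genes (Fisher's exact test, two-sided, p = 0.0169). The list medians were 2.9 and 50.1 CPM. The test treats genes as independent, and no human library was used here to show what gap human cells give. The difference therefore does not by itself point to another organism. MYC rose 1.20-fold, from 179 ± 22.6 to 215 ± 3.74 CPM (SD, n = 2; quasi-likelihood adjusted p = 0.0174), and lost its call without PBS replicate 2 (adjusted p = 0.29) and without csEV replicate 2 (adjusted p = 0.0941).

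**Figure D3:**
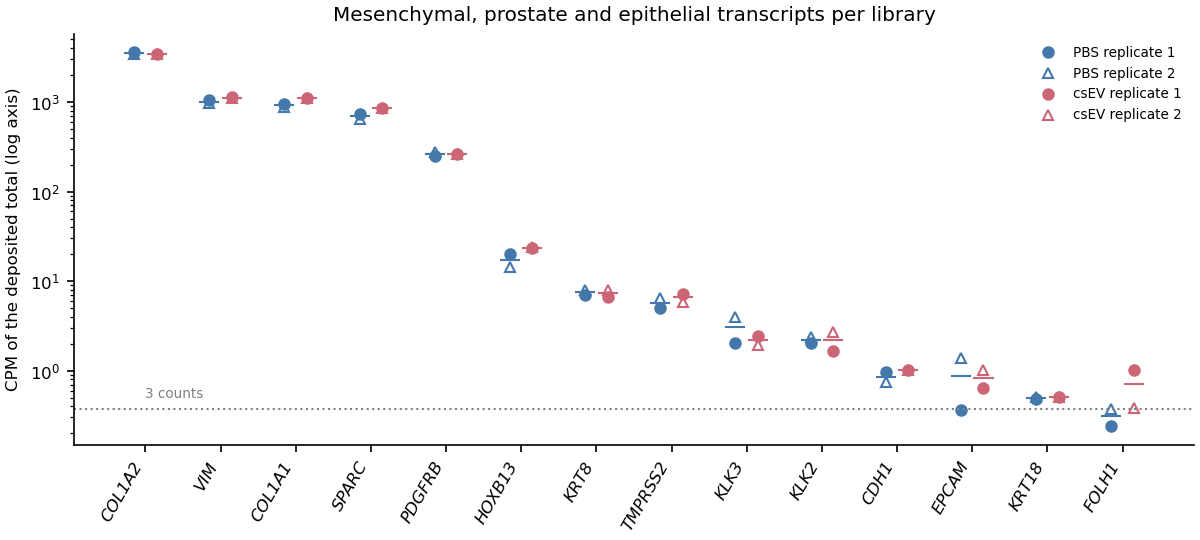
Levels in CPM of the deposited total, on a log axis, for mesenchymal, prostate and epithelial genes in each library (filled circles replicate 1, open triangles replicate 2, blue PBS, red csEV, short lines group means, dotted line 3 counts). PDGFRB, KRT8, KRT18 and EPCAM were added after their values were seen, and the group means of COL1A2 are 3520 CPM (PBS) and 3410 CPM (csEV) while KRT18 has 4 counts in each library.

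Markers of other cells gave no common shift with csEV. Of 11 tested leukocyte markers CD79A rose from 5.09 ± 0.00574 to 10.3 ± 1.87 CPM and ITGB2 fell from 36.0 ± 2.67 to 23.3 ± 1.95 CPM (SD, n = 2), and the list did not pass (camera adjusted p = 0.556). CD79A lost its call without PBS replicate 1, PBS replicate 2 or csEV replicate 1 (quasi-likelihood adjusted p = 0.0807, 0.119 and 0.0761), and ITGB2 without PBS replicate 1 or PBS replicate 2 (adjusted p = 0.0607 and 0.0529). SRGN, the most abundant of them, stood at 116 ± 15.5 and 106 ± 9.22 CPM (SD, n = 2; quasi-likelihood adjusted p = 0.408). In the fibroblast and smooth muscle list 2 of 9 rose, COL1A1 and COL3A1 (camera adjusted p = 0.546), of which neither passed without PBS replicate 2 and COL3A1 did not pass without csEV replicate 1, and the platelet (6 tested; camera adjusted p = 0.546) and endothelial (9 tested; camera adjusted p = 0.733) lists did not pass either. Erythroid and hepatocyte markers had 4 and 3 tested members, too few for the list test, and CA1, the most abundant erythroid marker, stood at 9.58 ± 1.22 and 8.67 ± 1.10 CPM (SD, n = 2). Of 26 genes of small vesicle biogenesis 2 rose and 2 fell (camera adjusted p = 0.596). The vesicle tetraspanin CD81 rose from 119 ± 6.95 to 144 ± 7.51 CPM and CD9 stood at 11.8 ± 3.05 and 11.3 ± 0.245 CPM (SD, n = 2). CD63 lost its call without PBS replicate 2 (quasi-likelihood adjusted p = 0.08) and CD81 lost its call without PBS replicate 1, PBS replicate 2 or csEV replicate 1 (adjusted p = 0.144, 0.0808 and 0.237). Of 37 genes of endocytosis 2 rose and 5 fell (camera adjusted p = 0.946). In these lists of vesicle biogenesis and endocytosis 0 members passed the quasi-likelihood test without PBS replicate 2. In all, 13 of the 49 lists tested passed, 7 upward and 6 downward, and 36 did not. With an estimated correlation 0 lists passed camera, where 2 had an unadjusted p under 0.05, and 0 passed fry, where 16 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0814.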

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

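The crossed block, the correction for GC content, length and expression and the counts of list members without each library were chosen only after the results were seen. The 1201 calls (638 higher, 563 lower, 63 at least 2-fold) had the same sign in every alternative run, and the count stayed between 1144 and 1305 with RLE or upper-quartile factors, library size alone, a filter of 1 CPM, limma-voom or robust quasi-likelihood. The larger direction turned with the scaling: upper-quartile factors gave 610 higher and 651 lower, and library size alone 697 and 447. The median log2 fold change of all genes moved between -0.01 and 0.01 over the scalings. DESeq2 called 544 genes (292 higher, 252 lower, 22 at least 2-fold), all among the 1201. A test of every gene with a count called 371 (224 higher, 147 lower, 33 at least 2-fold) over 17818 genes, and the cause was not tested. Leaving out 1 library gave between 125 and 663 calls (84 to 378 higher, 41 to 312 lower, 21 to 67 at least 2-fold) with fewer samples. The lowest count was without PBS replicate 2, where 124 of the 125 genes were among the 1201. Of the 136 named genes past the threshold, 105 lost their call without PBS replicate 2, 48 without PBS replicate 1, 46 without csEV replicate 1, 42 without csEV replicate 2, 68 in the test of every gene with a count and 35 with DESeq2, which gave no adjusted p for another 13 of them, among them CD68 and PLCXD2. An adjusted p under 0.1 added 27 named genes, and no called gene or list became a call in the opposite direction. The median of the glycolysis list turned from -0.08 to 0.02 without PBS replicate 2, and some lists that did not pass, such as endocytosis and prostate luminal identity, changed direction in some alternatives.

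The labels do not say that the replicate numbers mark a shared day or batch. With the replicate block 601 genes passed (353 higher, 248 lower), all among the 1201, and 40 named genes lost their call. The lists of TGF-beta targets and of autophagy did not pass under the block (camera adjusted p = 0.053 for each), and the other 11 did. The differences of replicate 2 from replicate 1 in the csEV group and in the PBS group had a Pearson's r of -0.155 across 7800 genes, and with crossed numbers the block called 1949 genes (1025 higher, 924 lower). The cause was not tested.

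Of the 13 lists past camera, 0 passed camera with an estimated correlation (smallest adjusted p = 0.648; 2 lists with an unadjusted p under 0.05) and 0 passed fry (smallest adjusted p = 0.0814; 16 lists with an unadjusted p under 0.05). The simulated list was missed by both tests too. Its genes were drawn independently and raised by only 0.3, so it does not show why the real lists did not pass. The estimated correlation was 0.527 for the mitosis list, 0.667 for S phase and 0.84 for glycolysis, against the preset 0.01. It was -0.0259 for the heat shock list and -0.0118 for the adhesion list, which did not pass with it either. Between 8 and 12 lists passed with 1 library left out, and 13 or 14 with other factors, another filter, cameraPR or the GC and length correction. The correction ended the call of the heat shock list (adjusted p = 0.0689; median -0.11 before and -0.10 after), and the cause was not tested. With the correction the mesenchymal genes and the actin and SRF targets passed (cameraPR adjusted p = 0.00786 and 0.00749). The mesenchymal list passed cameraPR without the correction too (adjusted p = 0.0396), while the actin and SRF targets did not (cameraPR adjusted p = 0.0749). The tests say little on genes of few counts, and 5920 genes were not tested. Among them FOLH1, CDH1, EPCAM and KRT18 (the last 2 chosen after their values were seen) lie near the 3-count floor. There a difference between the groups was not detectable. Why these genes were so low was not settled, and depth was not tested as the reason.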

Other observations

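The scan of gene families below, the levels of single mitochondrial genes and the tests of growth state, of 1 deciding library, of blood-cell RNA and of paralogs were chosen only after the results were seen. All genes named in this paragraph were likewise chosen after their values were seen. Among 411 families of at least 5 tested genes that share a symbol stem, 13 passed camera, 8 upward and 5 downward, and all had an adjusted p = 0.999 with an estimated correlation. All 7 tested guanylate-binding proteins rose (GBP; median 0.97 on the log2 scale, camera adjusted p = 4.29e-14), among them GBP4, which reached 42.9 ± 1.07 CPM with csEV (SD, n = 2; log2 fold change 1.03, quasi-likelihood adjusted p = 2.84e-06). Of 8 galectin genes and their binding partners, 4 rose (LGALS; median 0.48, camera adjusted p = 5.07e-05). LGALS3BP, a secreted glycoprotein, rose from 336 ± 5.29 to 420 ± 8.68 CPM (SD, n = 2; quasi-likelihood adjusted p = 0.000165). Of 11 PARP genes 4 rose (median 0.25, camera adjusted p = 0.0169), among them PARP14, with a log2 fold change of 0.55 (quasi-likelihood adjusted p = 6.73e-05). Of 33 kinesins 10 rose (KIF; median 0.15, camera adjusted p = 2.27e-06). Of 11 UTP genes of the small-subunit processome 4 fell and 7 did not pass (median -0.14, camera adjusted p = 0.0391), among them UTP15 at -0.34 and UTP20 at -0.21. GBP and LGALS genes have close paralogs, and the kinesin and GBP families overlap the mitosis and interferon lists.

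Mitochondrially encoded genes had very unequal levels within each library. Counts lay between 17628 and 19755 for MT-CO1, between 14851 and 17369 for MT-CYB and between 7534 and 8098 for MT-ND6, against 192 to 226 for MT-ND4, 0 to 4 for MT-CO2, 1 to 4 for MT-ATP6 and 0 to 2 for MT-ND3. Of the 13 genes 8 were tested and 1, MT-CYB, fell (camera adjusted p = 0.155 for the list). MT-CYB lost this call without each library in turn, with DESeq2 and with the replicate block (adjusted p from 0.0798 to 0.177).

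Mitotic genes were higher after csEV (list median 0.74). The values argue against a single library as the cause, since the lowest median with 1 library left out was 0.655. They also argue against a trend over GC content or gene length, since the median was 0.723 once that trend was removed. Across genes there was little trend to remove (Spearman's rho of the log2 fold change 0.0492 with GC content and 0.00966 with exonic length). Dishes at different growth states remain open: the PBS libraries differed in this list by 0.177 and the csEV libraries by -0.03, less than the groups, but with 2 libraries per group the variation between untreated cultures is poorly known. An effect of csEV on the cell cycle and a difference in growth state could both give this pattern and cannot be told apart here.

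Interferon-response genes were higher after csEV (list median 0.76). RNA of blood cells carried by the vesicles is argued against only as the source of the whole rise. The summed CPM of the leukocyte markers changed by -18.4 while the interferon list gained 647 CPM, a ratio of -2.85%. The sum includes genes expressed with PBS too, such as SRGN and ITGB2, which had lower means with csEV, whereas CD79A rose. Such changes could hide a smaller amount of carried RNA, which stays open. A trend over GC content or length is argued against too (median 0.752 after removal of the trend, which was small across genes). Reads shared between paralogs stay open for part of the list. Outside the IFIT, OAS, GBP, HLA, MX and IFI44 families 56.2% of members rose (9 of 16, 95% exact binomial interval 29.9% to 80.2%). Of all 12740 tested genes 638 rose, so the rise was not confined to those families. The interval treats members as independent, which genes measured in the same 4 libraries are not. A response to the vesicles, or to something isolated with them, may be the source. No control preparation without vesicles was used here to separate these. A difference between dishes is open as well. The PBS libraries differed in this list by 0.093, but 2 libraries per group show little of how untreated cultures vary.

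All 4 libraries had few prostate epithelial transcripts and many mesenchymal ones, in both groups. In lists written before the test, 34.4% of 32 genes without a rodent counterpart lay under 1 CPM against 9.09% of 33 conserved partner genes (Fisher's exact test, two-sided, p = 0.0169). Outside the MHC the shares were 28.6% of 28 and 6.45% of 31 (Fisher's exact test, two-sided, p = 0.0363). Reads from another organism could lower such genes, but so could human cells that do not express them, and 34.4% lies between the bounds set for and against the first explanation, which is also open, and untested, for the unequal mitochondrial counts and the counts at IFIT1B and GSTA5. No human library counted the same way was used here. This test therefore cannot tell apart reads from another organism, human mesenchymal cells and a mesenchymal state of the subline. It did not weigh the unequal mitochondrial counts, which were seen in all 4 libraries and for which neither mesenchymal explanation makes a prediction.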
